A study of Homo sapiens with 773 samples.

How the data were processed

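Cell-free DNA was extracted from serum, bisulfite-converted, and captured with padlock probes (molecular inversion probes, oligonucleotides that circularise around a target), then amplified and sequenced with paired-end reads, per the labels' protocols. Bisulfite converts unmethylated cytosine to uracil, so that the share of cytosine left at a CpG reads as its methylation level. Per the submitters' processing notes, Trim Galore, cutadapt 1.4.1 and Bowtie2 were used and the genome build was hg19. The methylation caller, its minimum coverage and the reason why a value is missing are not given in the sources used here. The authors deposited 1 table of methylation fraction values between 0 and 1, with 773 samples and 888 regions and no normalization stated. Exact values of 0 made up 16.9% of the 481390 values and exact values of 1 made up 11.0%. Without read counts or coverage, no coverage minimum, binomial interval or count test could be applied, and a value from few reads weighs the same as a value from many.

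Regions are named in the deposited table by a chromosome and a number. The number was read as the index of a 100 bp bin, because multiplied by 100 it spanned each chromosome. On 3 chromosomes (9, 10 and 22) the highest product lay beyond the last GRCh38 gene. A chromosome can extend past its last gene, so this alone does not exclude GRCh38 positions. The build was taken from the submitters' processing notes, which name hg19. Printed positions are the index times 100 in hg19, and each bin ends 100 bp further on. Whether bins count from 0 or 1 is not stated, so positions may be off by 1 bin. In 12 column names a spreadsheet had turned the name into a date. These regions were used for levels and left out of pairs of regions and of everything else that needs a position, except the correlations of single regions with the axis, where no chromosome could be left out for them and the axis included the region itself if kept. Without them, 40.1% of the kept regions rose with the axis and 39.8% fell, against 39.6% and 40.2% with them. Another 19 columns held no value in any sample and were not used. An annotation of the hg19 build was not used here, so regions were not assigned to genes, promoters or CpG islands. The gene list tests and the promoter comparison that had been fixed in advance were therefore not run.

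All 773 samples were placed in 1 group by their titles, 1 patient each. Regions with a value in at least 90% of patients (361 of 869) were used for all comparisons in the report, and 4 of them carried a date as name. The other 508 regions were used only where stated. Missing values were left out of means and set to the region's median for principal components. Low-level regions had a median under 0.2 (155 regions), high-level regions a median over 0.8 (165 regions), and 135 regions had a median under 0.1. Leaving out patients with over 10% of values missing was read as over the kept regions, which left 699 patients. Named regions were chosen by rules fixed before the data were examined: the 10 with the largest SD, the 5 with the lowest and the 5 with the highest mean, and the 10 regions with a median under 0.1 that had the most patients over 0.2. Regions named in the account of adjoining pairs and in the closing section were chosen after their values were seen. Correlations across patients are Pearson's r and Spearman's rho with two-sided permutation tests of 100000 resamples, 95% intervals from 1000 bootstrap draws of patients, and Benjamini-Hochberg adjustment over the 6 relations computed. The co-variation of adjoining regions was tested by 1000 one-sided permutations of positions. P-values of the correlations refer to no association across these patients. The p-value of adjoining regions refers to positions shuffled over regions, with the patients' values fixed. Work was done with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

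Samples were divided into 2 clusters by their pattern of missing values. The cause of the pattern is not given in the sources used here, and the number of clusters was set and not tested. The second principal component of the pattern of missing values was used to divide samples into clusters of 465 and 308. Along the numbers in the sample titles, cluster membership changed 66 times, against a median of 371 when shuffled. The mean share of missing regions was 26.7% in the first and 30.8% in the second cluster, and 46 regions differed by over 50 percentage points in the share of patients measured. The division was made from these same missing values. Median low-level means were 0.0511 and 0.0535, and median high-level means 0.934 and 0.933. Levels differed between the clusters in 48 of the 361 regions (two-sided permutation test of ranks with 100000 resamples, Benjamini-Hochberg adjusted p under 0.05), with a median absolute difference of 0.00645 between the means. The mean level differed by over 0.05 in 1 region, on chromosome 12 near 7276700 (0.359 and 0.442). Relations across patients were therefore also computed within each cluster.

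The statistics were tested on simulated data with the real missing values and 361 regions. With a simulated admixture that changed 200 regions, r between low-level and high-level means was -0.987, 100% of the changed regions were recovered, and 3 of 161 unchanged regions were called. With no admixture, r was -0.0537 (permutation p = 0.141) and 0 of 361 regions were called. Both simulations assumed a read depth and independent counting error, and the admixture moved each changed region by a large fixed amount. It raised the changed regions of lower level and lowered those of higher level, so the negative r was built in. The real depth is unknown and real changes can be smaller, so these rates do not show how often the tests are right in the real data. In the admixture simulation adjoining pairs, simulated with no shared signal of their own, had a median rho of 0.0251 and a permutation p of 0.004975, the smallest that 200 permutations can give, since neighbours share a level class; the p of the test on positions therefore does not separate the 2, and the size of the correlation and its value with the axis held constant are given with it. Alternatives to the thresholds, the required share of patients, the scale, the correlation coefficient and the patients included were recomputed.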

Results

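DNA methylation was measured in cell-free DNA, the short DNA fragments that circulate in blood, taken from the serum of 773 patients with colon cancer. Each sample stood for a different patient, and all samples belonged to 1 group. A panel of 888 short genomic regions was captured after bisulfite conversion, and each region received 1 methylation level per patient, a fraction between 0 and 1. Of these regions, 869 held a value in at least 1 patient. The median patient lacked a value in 27.8% of the 869 regions, with quartiles of 19.2% and 35.2% and a range of 5.98% to 64.8%. The comparisons below used the 41.5% of regions that were measured in at least 90% of patients, all of them autosomal, and these are called the kept regions. The number of patients behind each mean is given as the share of the 773 patients measured. The read depth behind the values was unknown, so no counting error could be attached to single values. The SD over patients is given as the spread between patients, counting error included, and not as the precision of a mean. Control samples and clinical outcomes were not analysed here, so the comparisons are between regions and across patients.

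The first question was which parts of the panel were methylated in the serum DNA of these patients. The panel split into an unmethylated and a methylated part. The mean level over patients was under 0.2 in 40.7% of the kept regions, over 0.8 in 44% and between these limits in 15.2%. The intermediate part depended on the limits. The kept regions in it made up 6.33% of all 869 regions with these limits, 15.07% with 0.1 and 0.9, and 2.88% with 0.3 and 0.7. The 6.33% and the 15.2% stand for the same regions over different totals. Regions of the unmethylated part had a median level of 0.0476, and those of the methylated part a median of 0.926. At the bottom of the range, 78 regions had a mean under 0.05, and at the top 49 had a mean over 0.95. The 5 regions with the lowest means lay on chromosomes 10, 12, 3, 20 and 1 (hg19), starting near positions 33269500, 121476700, 150321200, 30311900 and 24018400. Their mean levels were 0.00579 ± 0.0201 (SD), 0.00597 ± 0.0238, 0.00604 ± 0.0158, 0.00663 ± 0.0146 and 0.00690 ± 0.0131, each measured in 91.7% to 96.2% of patients, and the median patient was at 0 in each. The 5 regions with the highest means lay on chromosome 17 near 80798200, chromosome 16 near 89294200, chromosome 22 near 22288400, chromosome 14 near 103803100 and chromosome 11 near 71185100. Their means were 0.981 ± 0.0442 (SD), 0.980 ± 0.0195, 0.977 ± 0.0222, 0.976 ± 0.0383 and 0.976 ± 0.0450, each measured in 91.3% to 98.3% of patients. Regions measured in fewer than 90% of patients split in a similar way, with 40.2% of means under 0.2, 43.5% over 0.8 and 16.3% in between.

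**Figure D1:**
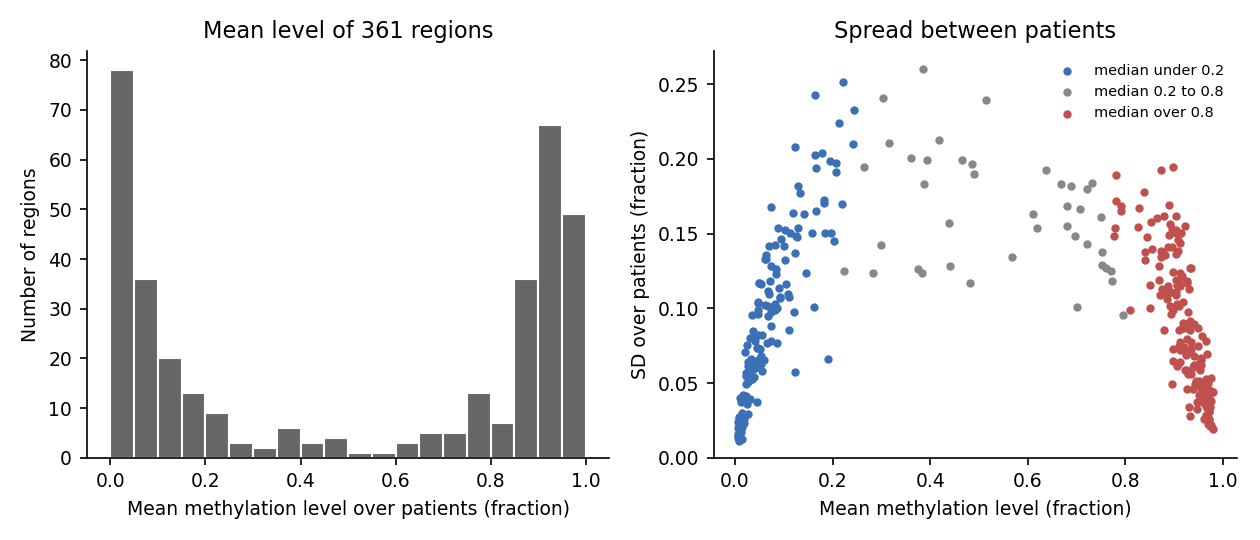
Left, the number of kept regions (y axis) by mean methylation level over patients (x axis, fraction). Right, the standard deviation over patients (y axis, fraction) against the mean level (x axis, fraction), 1 point per region, coloured by whether the median over patients was under 0.2, over 0.8 or in between; spread is smallest near 0 and 1, and the median standard deviation is 0.0752 for means under 0.2, 0.0777 for means over 0.8 and 0.169 in between.

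The next question was which regions differed most between patients. Spread was largest in the intermediate regions, with a median SD of 0.169, against 0.0752 in the unmethylated and 0.0777 in the methylated part. A fraction has less room to vary near 0 and 1, and counting error is largest at middle levels. Without the read depth, the ranking by SD does not separate these effects from differences between patients. The most variable region lay on chromosome 16 near 29757300, with a mean of 0.385 ± 0.260 (SD, 97.02% of patients measured) and quartiles of 0.179 and 0.555. A pair of adjoining regions on chromosome 6, near 31527800 and 31527900 and within the major histocompatibility complex, followed with means of 0.222 ± 0.252 (SD, 97.3% measured) and 0.165 ± 0.243 (SD, 92.8% measured). Their medians were only 0.117 and 0.0577, and 14.6% and 11.2% of the patients measured were over 0.5. The chromosome 19 region near 36233400 stood at 0.303 ± 0.240 (SD, 97.02% measured), the chromosome 2 region near 113931500 at 0.244 ± 0.233 (SD, 96.5% measured) and the chromosome 3 region near 118955800 at 0.213 ± 0.224 (SD, 92.9% measured). The chromosome 21 region near 36421400 had a mean of 0.242 ± 0.210 (SD, 99.7% measured), with 12.6% of patients over 0.5. The chromosome 8 region near 129005500 and the chromosome 17 region near 55456500 had means of 0.419 ± 0.213 (SD, 94.3% measured) and 0.316 ± 0.211 (SD, 98.4% measured). Another region on chromosome 17, near 75539800, had a mean of 0.515 ± 0.239 (SD, 99.7% measured) and quartiles of 0.349 and 0.714.

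Patients with higher methylation in the mostly unmethylated regions had lower methylation in the mostly methylated regions. Low-level regions were defined by a median under 0.2 (42.9% of the kept regions) and high-level regions by a median over 0.8 (45.7%), and each patient's mean was taken over each class. The low-level mean was 0.0718 ± 0.0505 (SD, n = 773), with a median of 0.0519 and a 95th percentile of 0.187. The high-level mean was 0.918 ± 0.0463 (SD, n = 773), with a median of 0.933 and a 5th percentile of 0.805. Across the 773 patients both means were negatively correlated, with a Pearson r of -0.807 (95% bootstrap interval -0.843 to -0.767) and a Spearman rho of -0.800. The two-sided permutation p was 1e-05 for each, the smallest that 100000 resamples can give. After Benjamini-Hochberg adjustment over 6 relations the permutation p was 2e-05 for r and 1.5e-05 for rho. Without the 2 patients farthest from the median low-level mean, r was -0.803. Samples were divided into 2 clusters by which regions lacked a value, and r was -0.821 in the first cluster (60.2% of patients) and -0.785 in the second (39.8%). With each patient's median over regions in place of the mean, r was -0.442. The same contrast appeared between single regions on different chromosomes: the median rho was 0.0732 for pairs of low-level regions, 0.0784 for pairs of high-level regions and -0.0547 for a low-level with a high-level region.

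**Figure D2:**
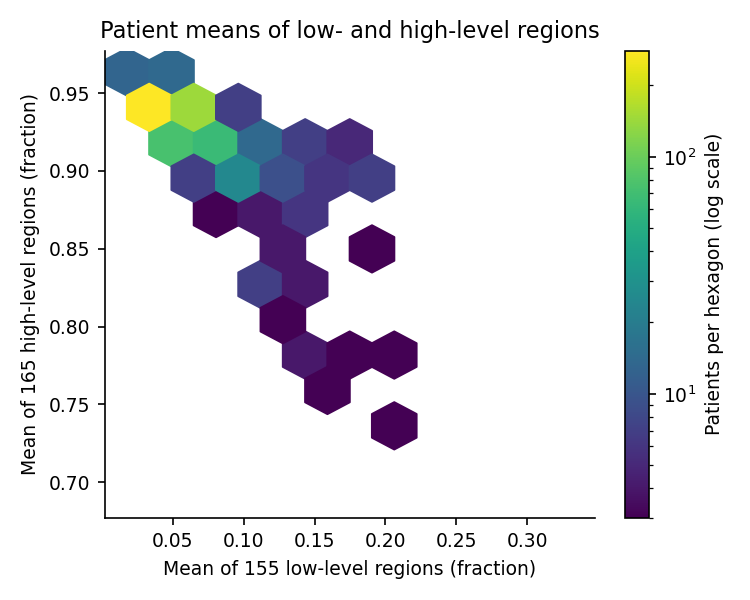
Each patient's mean level over the high-level regions (y axis, fraction) against the mean over the low-level regions (x axis, fraction), drawn as hexagons coloured by the number of patients on a log scale. Hexagons with fewer than 3 patients are not drawn, which leaves 94% of the 773 patients; most sit near the medians of 0.0519 and 0.933, and a tail runs to higher low-level and lower high-level means (r = -0.807 over all patients).

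High values in regions that were unmethylated in the median patient were then counted. Among regions with a median under 0.1, which made up 37.4% of the kept regions, 30 were over 0.2 in more than 10% of the patients measured, 36 in under 1%, and 13 of these in none. The median region was over 0.2 in 26 patients, and over the upper quartile plus 3 interquartile ranges in 28, and the number depended on the limit (80 over 0.1 and 11 over 0.3) and on the regions (17 for a median under 0.05). The region with the most such patients lay on chromosome 16 near 90092800, with 27.6% of the patients measured over 0.2 and a mean of 0.165 ± 0.194 (SD, 95.7% measured). The chromosome 6 region near 31527900 followed with 25.2%, and then an adjoining pair on chromosome 7 near 35301100 and 35301200 had 22.6% and 19.05%. A region on chromosome 7 near 150212900 was over 0.2 in 20.9% of patients, one on chromosome 10 near 101606000 in 19.8%, one on chromosome 1 near 92150500 in 17.3% and one on chromosome 7 near 54612300 in 16.2%. An adjoining pair on chromosome 5 near 167532400 and 167532500 was over 0.2 in 16.7% and 17.8%. Per patient, the median number of these regions over 0.2 was 3, with quartiles of 1 and 9, and 20.96% of patients had none. At least 10 such regions were found in 23.9% of patients, against a median of 20.2% and a highest value of 21.99% in 100 shuffles of the values between patients within each region. At least 20 were found in 13.2% of patients and in at most 0.129% in the shuffles, a limit that was chosen after the result at 10 had been seen. The shuffles also separated adjoining regions, which can vary together, so part of the excess may be a shared signal counted in each of them. These regions also enter the low-level mean, so the excess is not separate from the tail of that mean.

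Adjoining regions varied together. Among the kept regions, 98 pairs lay within 1000 bp of each other, and all of them were 1 bin (100 bp) apart. Their median Spearman rho over patients was 0.436, with quartiles of 0.232 and 0.616, against 0.0094 for the 59743 pairs on different chromosomes, with quartiles of -0.0619 and 0.0835. The size depended on the coefficient, with a median of 0.684 over the same 98 pairs for Pearson's r. A one-sided permutation of positions over regions gave p = 0.000999, the smallest that 1000 resamples can give, which a shared level class can also produce. The highest correlations were those on chromosome 21 near 36421400 and 36421500 (rho 0.954), chromosome 8 near 20375500 and 20375600 (rho 0.945), chromosome 13 near 111160300 and 111160400 (rho 0.918) and chromosome 16 near 90092700 and 90092800 (rho 0.907). Levels of adjoining regions were also close, with a median difference of 0.016 between their means, against 0.424 for pairs on different chromosomes. The pair on chromosome 12 near 132269500 and 132269600 differed most, with means of 0.950 and 0.733. With the low-level minus high-level mean of each patient held constant, the median rho of adjoining pairs was 0.404. A sequencing read can span adjoining bins, so the values of a pair need not be independent measurements.

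**Figure D3:**
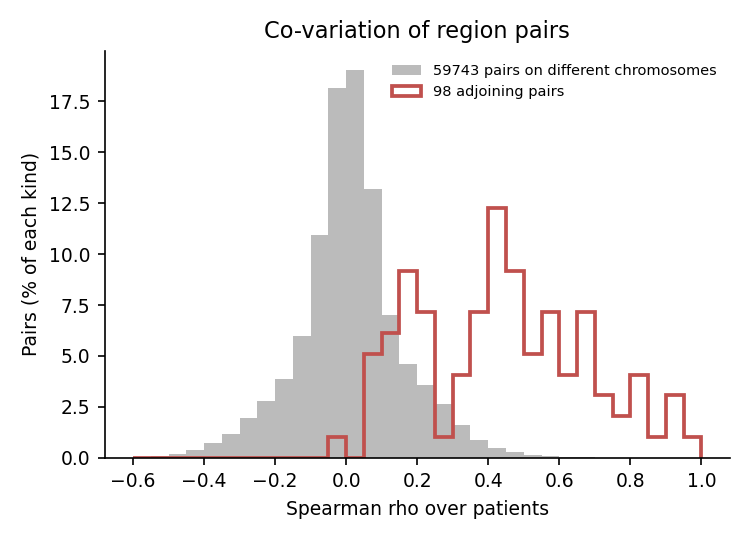
Distribution of Spearman rho over patients (x axis) as a percentage of the region pairs of each kind (y axis), for the 98 adjoining pairs and the 59743 pairs on different chromosomes. Adjoining pairs have a median of 0.436 and pairs on different chromosomes a median of 0.0094.

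A principal component analysis of the kept regions was used to look for a dominant difference between patients. The first 5 components held 20.2%, 7.29%, 2.55%, 2.09% and 1.70% of the variance of the scaled regions, and the share of the first depended on scaling (35.45% without it) and on the regions used (45.07% over the 24 complete in every patient). The first component followed each patient's low-level mean minus the high-level mean (Pearson r 0.984, Spearman rho 0.985, permutation p = 1e-05 for both, adjusted 2e-05 and 1.5e-05). This r was 0.987 without the 2 patients farthest from the median, and 0.981 and 0.993 within the clusters of missing values. The component and this difference were computed from the same regions in the same patients. Their correlation is therefore partly built in, and its p-value is no test of a separate relation. The mean over all kept regions shares its values with the component too. With the mean over all kept regions the first component had a Pearson r of 0.00718 (permutation p = 0.84, adjusted 0.84) but a Spearman rho of 0.249 (permutation p = 1e-05, adjusted 1.5e-05). That r was 0.00851 without the 2 patients farthest from the median, and 0.0638 and -0.101 within the clusters, and that rho was 0.276 and 0.196. With the share of regions lacking a value the first component had a Pearson r of 0.0712 (permutation p = 0.0472, adjusted 0.0566) and a Spearman rho of 0.0739 (permutation p = 0.0401, adjusted 0.0401). This r was 0.0673 without the 2 patients farthest from the median, and 0.137 and -0.129 within the clusters, so the relation did not keep its direction. None of the 298378 pairs of samples had identical values, and the highest correlation between 2 samples was 0.997. The median pair was at 0.964, so this correlation could not tell a noisy repeat from 2 patients, and no sample was left out as a repeat.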

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

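In this part, the tests of incomplete conversion, of few measured values and of a general flattening, and the correlations of single regions with the axis, were chosen after the result they measure had been seen. The clusters by missing values were made from the data, and the limits for the tests within them and of admixture were written after the pattern but before the values tested.

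Regions measured in under 90% of patients entered no correlation in the report, yet many carried the same signal. Each patient was given an axis value, the low-level mean minus the high-level mean, computed without the chromosome of the region under test where that was known. Of such regions with at least 50 patients, 56.83% correlated with the axis (two-sided permutation test with 100000 resamples, Benjamini-Hochberg adjusted p under 0.05), 26.7% rising and 30.2% falling by the sign of rho (1 region had a least-squares slope of the opposite sign). In 100 shuffles of the axis between patients, tested with scipy's approximate p for Spearman's rho, at most 1 region passed. Among those with a median under 0.2, 45.9% rose and 1.03% fell, and among those with a median over 0.8, 57.1% fell and 2.76% rose. The regions with the highest correlations lay on chromosome 4 near 89766600 (rho 0.733, mean 0.367 ± 0.172 SD) and chromosome 10 near 14701800 (rho 0.707, mean 0.440 ± 0.194 SD).

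For the opposite movement of low-level and high-level regions across patients, the pattern behind these regions, incomplete bisulfite conversion as the whole cause, which would raise both, is argued against by r = -0.8068; few measured values by a rho of 0.0988 between the axis and the share of missing regions (adjusted permutation p = 0.00757; 0.127 and -0.037 within the 2 clusters by missing-value pattern); and these clusters, whose cause is unknown, by the weaker within-cluster r of -0.7853. A flattening of all regions alike toward a middle level would raise regions near 0 by about the same amount, but 37.78% of those with a median under 0.1 had a slope on the axis under 0.5 times their mean slope, judged by the 95% bootstrap interval of each (quartiles of the slopes 0.0321 and 0.642, mean 0.397). This was the last of 3 tests: the first, on 23 regions with means of 0.3 to 0.7 of which 4 moved away from 0.5 (17.4%), had decided nothing, and another was dropped because it divided regions by a mean that the rise itself sets. Region slopes fitted in odd-numbered and even-numbered patients correlated at r = 0.9912 across regions, which are not independent replicates. The pattern already seen gives low-level and high-level regions slopes of opposite sign, which by itself favours a high r in any split of patients. Any other influence with fixed slopes would give this too. A varying share of DNA from a source with another methylation profile is therefore only a candidate explanation, which this r could hardly have gone against. Whether such a source is tumour, another tissue or a different mix of blood cells stays open, because reference profiles, control samples and clinical labels were not analysed here and no biological explanation was tested.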

How the results depend on the processing

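The alternatives within the missing-value clusters, by odd and even chromosomes and by the median over regions were chosen after seeing the data; the others were planned. The negative correlation of low-level and high-level means kept its sign and a permutation p of 1e-05, the smallest possible, in all 11 alternatives, with r from -0.4417 (median over regions) to -0.8215. The median rho of adjoining regions ranged from 0.4296 to 0.7947 over the alternatives; its permutation p was 0.000999 in each, which shows no stability, since simulated neighbours with no shared signal of their own also reached the smallest p; distances of 200 and 10000 bp selected the same 98 pairs and tested nothing, and the highest median rests on the 8 pairs with means from 0.2 to 0.8. For the 29 named regions, neither alternative could by construction move a level by 1 SD over patients: the median in place of the mean changed 16 by over 1.5 times, 5 of them to 0 (for example chromosome 7 near 35301200 from 0.123 to 0.03704), and the patients with few missing values changed them by up to 0.01102. Counts of regions moved with their definition. As shares of all 869 regions, kept regions with low, intermediate and high means made up 16.92%, 6.329% and 18.3%. With no minimum share of patients, so that every region with a value was counted, the shares were 40.39%, 15.88% and 43.73%. With a value in at least 99% of patients they were 5.639%, 1.496% and 5.178%. The shares moved because more or fewer regions entered. Kept regions with intermediate means made up 15.07% of the 869 with thresholds of 0.1 and 0.9 and 2.877% with 0.3 and 0.7. The median number of patients in the right tail was 80 over 0.1, 11 over 0.3, and 17 for regions with a median under 0.05. The first component held 35.45% of the variance without scaling, 45.07% over the 24 regions complete in every patient, 21.67% in the 90.4% of patients with few missing values and 21.96% in the second cluster; the cause was not tested. With a sample correlation over 0.99 as the limit, 2834 pairs would count as duplicates, while the median pair was at 0.964. Alternatives for coverage, gene assignment, promoter windows and gene lists were not run, because neither coverage nor an hg19 annotation was used here. No paired analysis was possible because there was 1 group. Depth per value was unknown, which limits single levels near 0 or 1.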

Other observations

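In this part, the correlations of single regions with the axis were examined after the axis had been seen. The second set of regions was noticed, and the clusters by missing values were made, in all patients before the tests of the set were fixed. The test of incomplete conversion was chosen after the other results of the set had been seen.

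Most of the kept regions correlated with the axis, the low-level minus the high-level mean, but not all of them. The median rho was 0.250 over the low-level and -0.246 over the high-level regions, so passing the test did not mean a strong relation. Of the low-level regions, 76.8% rose and 22.6% did not pass the permutation test (Benjamini-Hochberg adjusted over the kept regions), with the direction taken from the sign of rho. With a mean under 0.03, 44% rose and 54% did not pass, against 92.4% and 7.62% of the others, a split by a mean that a rise itself raises. The chromosome 21 pair near 36421400 and 36421500 had the highest correlations (rho 0.788 and 0.772), followed by chromosome 11 near 70211500 (rho 0.744) and chromosome 6 near 31527800 (rho 0.728). The 1 low-level region that fell lay on chromosome 2 near 190526000 (rho -0.0997, mean 0.0109). Its level was near 0, with means of 0.0101 and 0.0119 in the first and second cluster by missing values. Its rho within the clusters is not given here, so this weak fall may not hold within them. Of the high-level regions 78.2% fell, with chromosome 18 near 61143900 (rho -0.700, mean 0.909), chromosome 22 near 45597700 (rho -0.636) and chromosome 6 near 170494200 (rho -0.634) lowest. The 4 high-level regions that rose lay on chromosome 2 near 179317200 (rho 0.201), chromosome 6 near 15281200 (rho 0.133), chromosome 5 near 125695600 (rho 0.109) and chromosome 22 near 22288400 (rho 0.0975). Of the 41 remaining regions 20 rose and 15 fell by rho, but 3 of the 20, on chromosome 14 near 91862800 and 91862900 and chromosome 6 near 16729600, had a least-squares slope below 0 (-0.177, -0.239 and -0.379), as had 1 low-level region, on chromosome 1 near 226085100 (-0.134), so their direction is not settled. Regions of like level differed: chromosome 16 near 29757300 (mean 0.385) had a rho of 0.708 and chromosome 17 near 48894900 (mean 0.383) a rho of -0.337.

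Among the 10 most variable regions, only the chromosome 17 region near 75539800 had a negative correlation with the axis. The axis correlated positively with the other 9, at rho from 0.576 to 0.788, and with this region at rho -0.176. Several of the other 9 were low-level regions, whose rise defines the axis, so their positive rho is partly built in. This region was one of the 41 that were neither low-level nor high-level. Of these 20 rose and 15 fell, so a negative rho was not particular to it. The adjoining region near 75539900 had a rho of -0.499 with the axis and a mean of 0.708 ± 0.166 (SD), and the rho between both regions was 0.538, or 0.527 with the axis held constant. Other variable regions with a weak relation to the axis lay on chromosome 8 near 126285400 (SD 0.192, rho -0.105) and chromosome 6 near 16729600 (SD 0.190, rho 0.124, slope -0.379).

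The second principal component pointed to a set of low-level regions that varied with the axis and in part beyond it: in the odd-numbered patients, the 20 low-level regions with its largest loadings were chosen, on 9 chromosomes and with means of 0.0297 to 0.203, among them chromosome 1 near 211500900, chromosome 8 near 49612400, chromosome 1 near 203595000 and chromosome 5 near 167532400. All 20 rose with the axis (rho 0.194 to 0.595), and in the even-numbered patients their mean had a rho of 0.676 with the other low-level mean and -0.547 with the high-level mean, or 0.0106 with the high-level mean when the other low-level mean was held constant. There, the means over odd-chromosome and even-chromosome members had a partial rho of 0.4525 with the other low-level and the high-level mean held constant. This was above all 1000 random sets of low-level regions (median 0.0959, highest 0.310). The random sets were not matched to the set by level or spread. The set had a median mean of 0.0833, while the low-level regions also include regions with means under 0.03. The excess over the random sets can therefore partly reflect how measurable the regions were. It argues against noise around the axis only as far as the random sets are comparable. The weaker partial rho within a cluster by missing-value pattern was 0.3667, against the clusters as the whole cause of the partial rho. Incomplete conversion of like size everywhere would add the variation beyond the axis to every low-level region. Of the regions outside the set with a median under 0.1, 45.3% had a covariance with the set's mean under 0.5 times the 0.00268 shared by its odd-chromosome and even-chromosome members beyond the axis, judged by 95% bootstrap intervals. The set was chosen by its largest loadings, which favours weaker covariance outside it. The result therefore speaks only against a failure of like size in every region, and an uneven failure was not tested. This test replaced another because that one held constant a mean which such a failure would raise too. As a hypothesis, another source of variation may exist beside the axis; the even-numbered patients are not fully independent evidence, since level classes and the component were first seen in all patients, and no biological explanation was tested.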
